A study of Mus musculus with 7 samples.

How the data were processed

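RNA from mouse embryos at stage E12.5 was measured by RNA sequencing of laser-captured surface ectoderm. The series holds 3 wild type libraries (replicates 2, 3 and 4) and 4 libraries from embryos lacking the microRNA miR-205 (replicates 1 to 4). Per the labels' protocols, frozen head sections were stained with hematoxylin, the ectoderm lying between the eye and the brain was cut out by its position and morphology, and 3 embryos were pooled for each library. The replicate is therefore a pool of embryos. cDNA was made with a template-switching kit for low RNA input and fragmented by tagmentation. Per the series' design text, a library from wild type replicate 1 was removed by the submitters because other tissue had been captured with it, which they judged from lower Pax6, Krt5 and other markers; that library was not analysed here.

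Per the submitters' processing notes, reads were mapped to the mouse genome GRCm38 with TopHat2 2.0.9, counted per Ensembl gene with HTSeq in its intersection-strict mode, and tested with DESeq2 at a false discovery rate of 0.1 over genes with normalized counts above 10 in each library. The strand setting of the counting is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Intersection-strict counting leaves out reads that reach beyond annotated exons, and reads from near-identical copies can be lost or split, so that values of ribosomal protein genes, histone genes, Erdr1 and Lars2 are uncertain. The deposited table lists 47729 Ensembl genes. Its signal columns are the authors' normalized counts, read counts divided by 1 size factor per library; its log2 column is the authors' moderated fold change of knockout over wild type; its p-value columns are the authors' DESeq2 p and adjusted p.

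In each library the smallest value above 0 was taken as 1 read. With that step 100% of the values above 0 were whole numbers of reads within 0.01 read, and the recovered totals were between 8903523 and 12504790 reads. The design fixed before the data were examined named a count test for counts and limma-trend for other values. Because the deposited values were normalized counts, limma-trend was the main test and the count tests on recovered reads were alternatives. For the same reason list scores were computed on log2(normalized count + 1), and the log2 CPM scale with prior count 2 became the alternative.

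The main test was limma-trend 3.58.1 (R 4.3.3) with robust moderation on log2(normalized count + 1), over the 15029 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.1. Fold changes are on that scale, which understates changes of weakly expressed genes. Gene lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation and fry beside it. The 26 lists covered miR-205 targets known from the literature, signalling pathways, ocular and glandular development, ectoderm, cell types that laser capture can include, proliferation, stress, mitochondrially encoded mRNAs and embryo sex. List scores are mean log2 values per library, compared with exact permutation tests; with 3 against 4 libraries the smallest two-sided p is 0.0571 and the smallest one-sided p is 0.0286.

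For the seed comparison, the longest annotated 3′ UTR of each gene was taken from GENCODE M21, which is on GRCm38. Of the 15029 tested genes, 13528 (90.0%) had a 3′ UTR of at least 30 nt and entered it; genes without an annotated 3′ UTR were not searched. A gene counted as a site gene if its 3′ UTR held ATGAAGG, the match to positions 2 to 8 of the mature miR-205-5p TCCTTCATTCCACCGGAGTCTG, whether or not an A followed (8mer or 7mer-m8). The score of a library was the mean log2 value of the 1666 site genes minus that of all other genes, tested one-sided for higher values in knockout with a threshold of 0.05. The comparison with matched genes used 20 classes of 3′ UTR length and 5 of mean expression. The 139 other 7-mers made of the same bases served as controls. Among them is TGAAGGA, the 7mer-A1 site of miR-205 (a shorter seed match followed by an A), so the controls are not free of its sites. The share of site genes among calls, its sets matched on 3′ UTR length and expression, and the comparison by class of site were added after seeing the data. Where leaving out libraries made p under 0.05 unreachable, the score was judged by whether it moved by less than the replicate SD.

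Genes named in the text were the miR-205 locus and its host transcript, the genes past the threshold with the largest changes or, where fewer than 5 passed in a direction, the 5 smallest p in it, up to 4 called members of each list or otherwise the 2 with the smallest p, 6 literature targets (Inppl1, Zeb1, Zeb2, Inpp4b, Phlda3 and Frk), and Pax6 and Krt5. Symbols of unnamed clones and pseudogenes were left out. The lists, this rule, the tests and most alternatives were chosen before the data were examined.

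Alternatives were edgeR 4.0.16 quasi-likelihood fits with 3 normalizations and without a filter, DESeq2 1.42.0 with and without shrunken coefficients, limma-voom with sample weights, other filters, pseudocounts of 0.5 and 5, other scalings, a replicate block, each library left out in turn, knockout libraries 1 and 2 left out together, and a covariate for depth (libraries over and under 10000000 reads). The last 2, TMM and upper-quartile scaling within limma-trend, the shrunken DESeq2 fit and the edgeR fit with TMM were added after seeing the data. That edgeR fit was the count test named in the fixed design, and only its use as an alternative on recovered reads was added.

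The tests were run on simulated counts with 200 of 15029 genes changed, 5 times, for knockout against wild type. Limma-trend found 21.2% of 1.5-fold, 50.1% of 2-fold and 77.3% of 4-fold changes, and 14.4% of its calls were false. DESeq2 found 31.6%, 58.8% and 85.8%, and 34.4% of its calls were false. For random sets of 1666 genes in 20 runs, the matched seed comparison gave a mean difference of -0.00028 (SD 0.012) without a shift and 0.0997 with a shift of 0.1 added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for scores and permutation tests.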

Results

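Surface ectoderm is the outer epithelium of the embryo, and its part beside the eye gives rise to the lacrimal gland, the gland that makes tears. The study asked what loss of miR-205, a microRNA of stratified epithelia, does to gene expression in this tissue at stage E12.5. Gene expression was measured in 3 wild type and 4 miR-205 knockout libraries, each from 3 pooled embryos. The wild type libraries held 8947136, 12504790 and 11287215 recovered reads for replicates 2, 3 and 4, and the knockout libraries held 8903523, 9444220, 11869658 and 11719631 reads for replicates 1 to 4. The number of genes with reads per library was between 19318 and 20713, and the correlation of log2 values between libraries was between 0.894 and 0.961. Wild type replicate 2 and knockout replicates 1 and 2 each had fewer than 10000000 reads, so both groups were represented at either depth.

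The targeted microRNA could not be checked directly. Mir205 (ENSMUSG00000065533) lies on chromosome 1 from 193507463 to 193507530 on the minus strand (GRCm38) and had 0 reads in all 7 libraries. It lies inside an exon of its host transcript on the same strand in GENCODE M21, where intersection-strict counting would leave it no reads of its own, so the 0 reads check nothing. The host transcript, 4631405K08Rik (ENSMUSG00000097850), a long noncoding RNA on chromosome 1 from 193507238 to 193510174 on the same strand, had 1419 ± 659 normalized counts in wild type (SD, n = 3) and 2884 ± 924 in knockout (SD, n = 4). Each knockout library lay above each wild type library, with a log2 difference of 1.11 (SE 0.44) and an adjusted p of 0.494 by limma-trend. With depth as a covariate, 4631405K08Rik had a log2 difference of 1.28 and passed 0.1 (adjusted p 0.0975); without wild type replicate 2 it had 0.63. Over all settings the difference was between 0.40 and 1.497 and the adjusted p between 0.0975 and 0.789. The counts do not tell whether the transcript carried the deletion, so they do not check the genotype labels.

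Among single genes, the smallest p with higher values in knockout belonged to Mgrn1, a ubiquitin ligase, with 1009 ± 96.4 normalized counts in wild type and 1587 ± 61.5 in knockout (log2 difference 0.66, SE 0.09). Rcbtb1 had 887 ± 36.9 and 1305 ± 76.2 (log2 difference 0.56). Nol4l had 218 ± 29.3 and 399 ± 24.6 (0.87). The cell adhesion gene Cadm1 had 1216 ± 111 and 1897 ± 202 (0.64). Flt4, the receptor of lymphatic endothelial growth factors, had 12.8 ± 0.636 and 63.3 ± 16.7 normalized counts (2.18, SE 0.37). The smallest p with lower values belonged to the linker histone gene Hist1h1e, with 837 ± 34.97 in wild type and 519 ± 16.8 in knockout (log2 difference -0.69, SE 0.09). Rpl22l1 had 1791 ± 74.7 and 1254 ± 93.0 (-0.52). Erdr1 had 204 ± 17.2 and 87.6 ± 14.0 (-1.22). The ribosomal protein gene Rps27a had 8767 ± 210 and 6935 ± 376 (-0.34), and Lars2 had 94209 ± 7019 and 70969 ± 5707 (-0.41). In all 10 genes the 4 knockout libraries lay on one side of the 3 wild type libraries, which their choice by smallest p in these libraries favours. Values of Hist1h1e, the ribosomal protein genes, Erdr1 and Lars2 may include or lack reads of near-identical sequences.

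None of the 15029 genes passed an adjusted p of 0.1 by limma-trend; the smallest adjusted p was 0.127, for Hist1h1e and Mgrn1, and 1469 genes had an unadjusted p under 0.05. The edgeR quasi-likelihood test on recovered reads called 0 genes with TMM and 11 without a filter, and DESeq2 called 227, of which 128 were higher and 99 lower. Without wild type replicate 2, limma-trend called 84 genes, 74 of them higher, and without knockout libraries 1 and 2 it called 3. In the authors' deposited table, 338 of 11933 genes with an adjusted p passed 0.1, 171 higher and 167 lower in knockout, with a median absolute log2 fold change of 0.41. Each of those 338 genes had an unadjusted limma-trend p under 0.05 in the same 7 libraries.

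**Figure D1:**
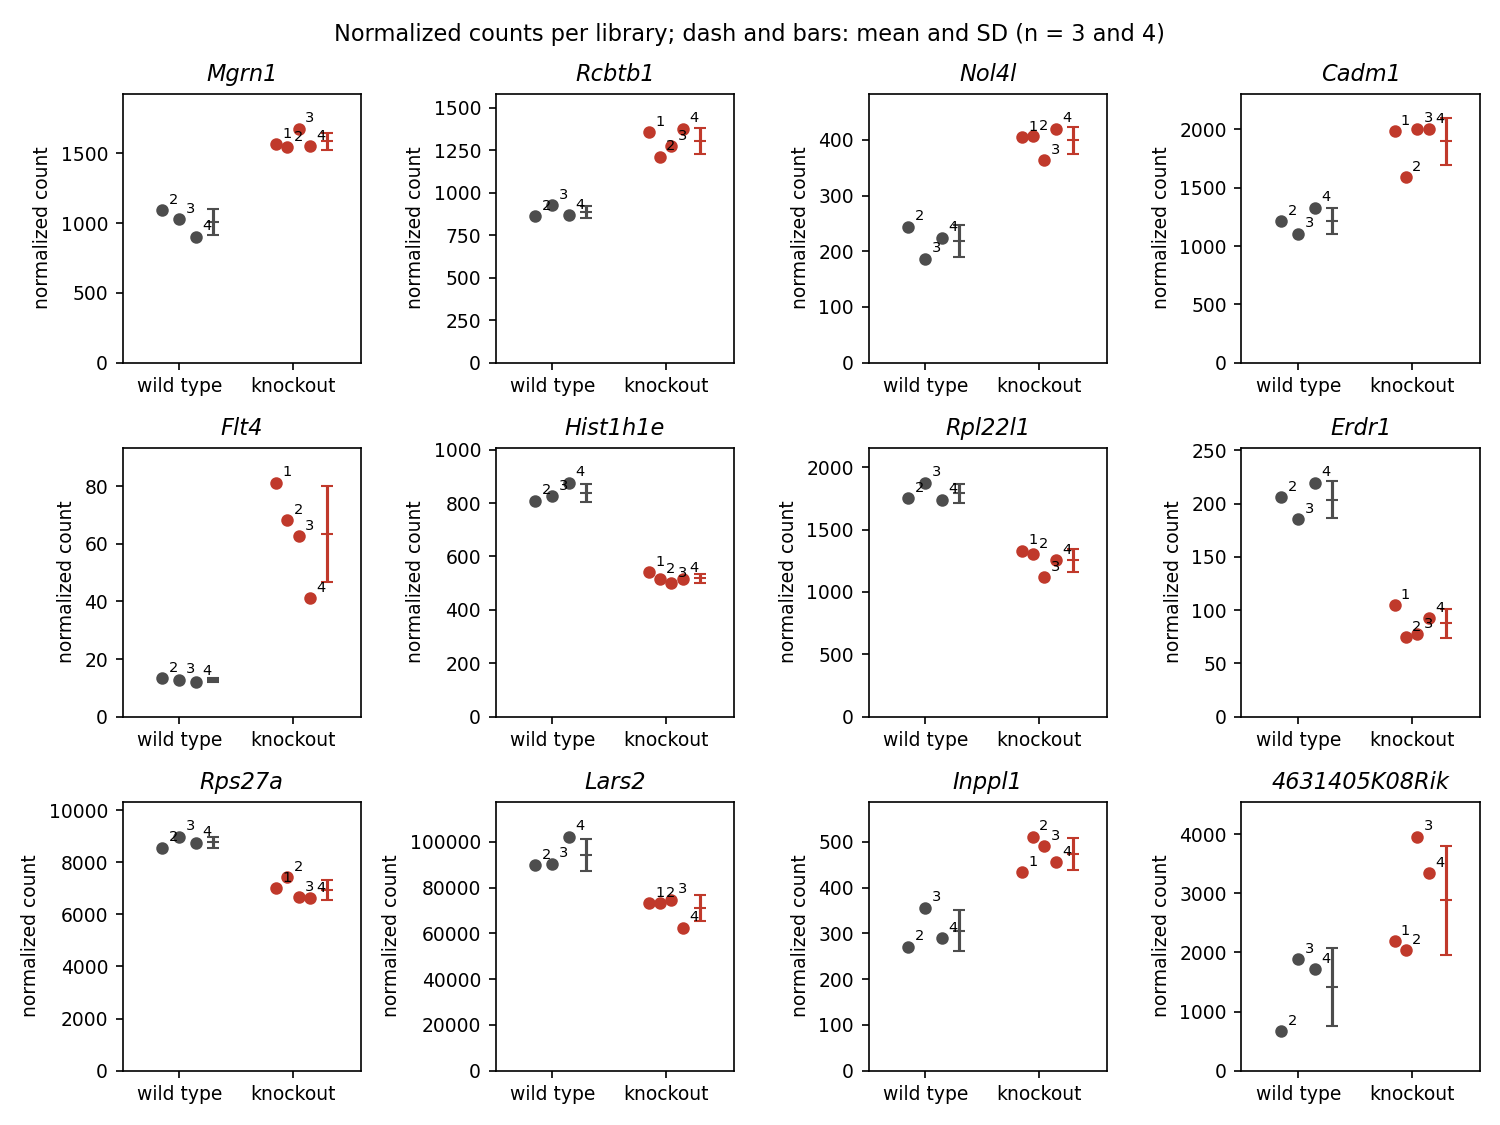
Normalized counts (vertical axes, starting at 0) of 10 genes (the 5 named genes with the smallest p in each direction), of Inppl1 and of the miR-205 host transcript 4631405K08Rik in each library. Replicate numbers stand beside the points and the mean and SD beside each group (3 wild type, 4 knockout). In each panel all knockout points lie on one side of the wild type points, as for Mgrn1 with 1009 ± 96.4 against 1587 ± 61.5.

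A microRNA lowers messages that carry a match to its seed, so the second comparison asked whether such messages were higher without miR-205. They were. The 1666 genes with an 8mer or 7mer-m8 site had a mean log2 value, relative to all other genes, of -0.138 ± 0.024 in wild type (SD, n = 3) and -0.073 ± 0.015 in knockout (SD, n = 4), a difference of 0.065. Each knockout library exceeded each wild type library (one-sided exact permutation p = 0.0286, the smallest this design can give). Within the 4 libraries over 10000000 reads the difference was 0.065 (one-sided exact permutation p = 0.167, the smallest these libraries can give). Within the 3 others, 1 of them wild type, it was 0.054. Of the site genes 61.0% had higher mean values in knockout, against 51.6% of the other genes. Only 1 of 139 control 7-mers of the same bases gave a difference as large; their median was 0.023. Site genes have longer 3′ UTRs (median 2574 against 1089 nt), and against genes matched on 3′ UTR length and expression the difference was 0.035, again with each knockout library above each wild type library. In matched comparisons the difference was 0.060 for the 598 genes with an 8mer, 0.023 for 1068 genes with a 7mer-m8 alone, whose libraries overlapped (one-sided exact permutation p = 0.0857). It was 0.0086 for 1342 genes with a 7mer-A1 alone (p = 0.257 by the same exact test).

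Of the 5 genes with the smallest p and higher values, 4 carried a site, against 0.887 on average in sets matched on 3′ UTR length and expression (permutation p = 0.0037). That permutation test drew genes and not libraries. Mgrn1 has 8mers, ATGAAGGA in the message, in its 3′ UTR on chromosome 16 with seed matches from 4937227 to 4937233 and from 4937376 to 4937382 (GRCm38, plus strand). The seed match of the 8mer of Rcbtb1 lies on chromosome 14 from 59235460 to 59235466 (plus strand), that of the 8mer of Cadm1 on chromosome 9 from 47853133 to 47853139 (plus strand), and that of the 7mer-m8 of Nol4l on chromosome 2 from 153408107 to 153408113 (minus strand), all in the 3′ UTR. Of the calls in the authors' deposited table with a 3′ UTR, 56 of 169 higher ones (33.1%) and 8 of 160 lower ones (5.0%) carried a site, against 1424 of 11487 listed genes (12.4%). Sets of genes matched on 3′ UTR length and expression held 26.7 site genes on average for the higher calls (permutation p = 0.0001 from 10000 random sets, the smallest they can give) and 11.3 for the lower calls (p = 0.180 for as few by the same permutation test). Genes and not libraries were drawn here too, so neither test takes in the variation between libraries, and genes that vary together count as separate. The calls came from the same libraries as the seed score and are no independent evidence.

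**Figure D2:**
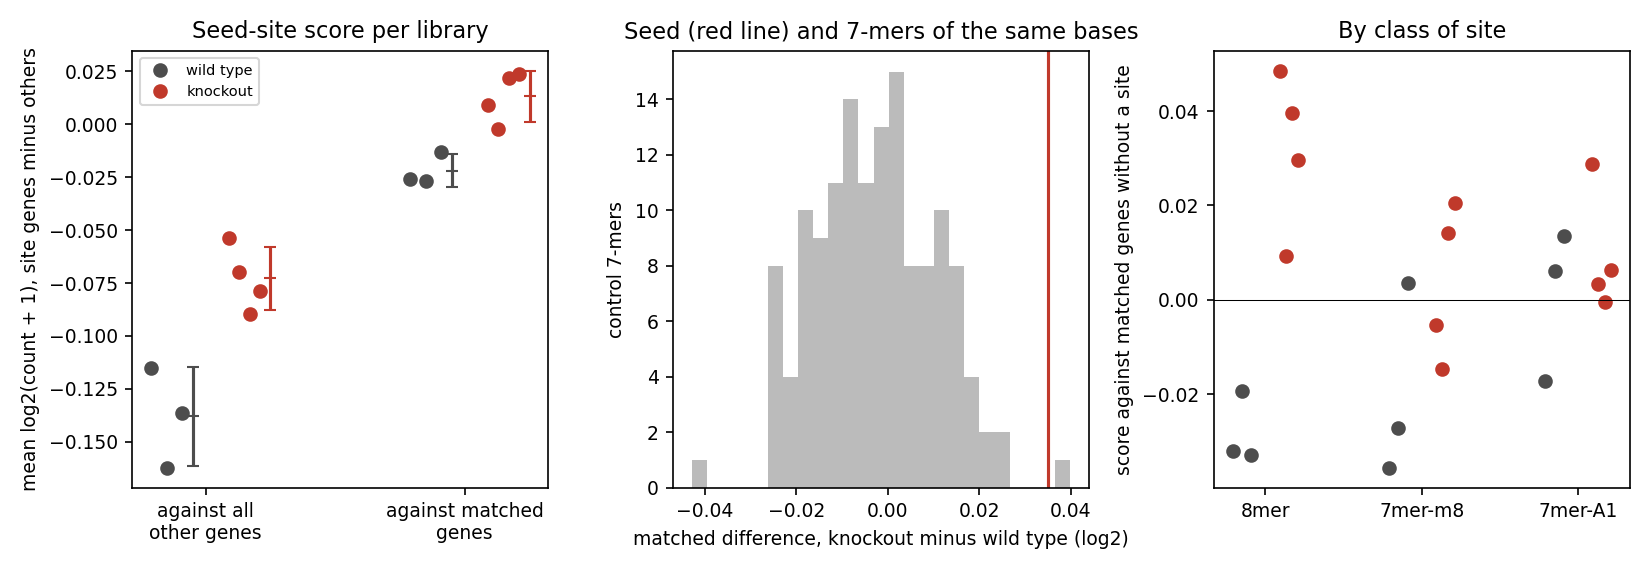
Left, mean log2(normalized count + 1) of miR-205 seed-site genes minus that of all other genes or of matched genes, 1 point per library with mean and SD; middle, the matched difference between knockout and wild type for the seed (red line, 0.035) and for 139 control 7-mers; right, the score of each class of site against matched genes without a site, per library. The knockout points lie above the wild type points in both comparisons on the left and for 8mers on the right.

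Targets of miR-205 known from the literature passed as a list. Of 26 such genes, 18 had higher and 8 lower mean values in knockout, with a median log2 difference of 0.12, and camera gave an adjusted p of 0.0746; with an estimated correlation the adjusted p was 0.699. Of the 13 with a seed site in the 3′ UTR 8 had higher values (median log2 difference 0.13), and of the 13 without one 10 had (0.065). Inppl1, which encodes the phosphoinositide phosphatase SHIP2, had 305 ± 44.8 normalized counts in wild type and 473 ± 34.4 in knockout (log2 difference 0.64, SE 0.13), and was the single gene of the list past 0.1 when adjusted over the list alone (adjusted p 0.0196), while 0 passed over all genes tested (adjusted p 0.312). The seed match of its 8mer lies in the 3′ UTR on chromosome 7 from 101822903 to 101822909 (minus strand). Amot had 226 ± 15.8 and 332 ± 57.9 normalized counts (0.54, SE 0.16). Zeb1 and Zeb2, repressors of epithelial genes, had log2 differences of 0.84 (SE 0.37) and 0.06 (SE 0.46). Inpp4b had 0.05 (SE 0.51), Frk 0.25 (SE 0.13) and Phlda3 -0.38 (SE 0.16), and their libraries overlapped between groups. Zeb1 had 87.7 normalized counts in wild type replicate 3 but 225 and 235 in replicates 2 and 4. Over all settings the log2 difference of Zeb1 was between 0.38 and 1.08. Of the 16 negative regulators of PI3K and AKT signalling, 13 had higher values, Inppl1 and Pik3ip1 (105 ± 12.2 against 155 ± 23.8) with the smallest p. Camera gave an adjusted p of 0.0679, and with an estimated correlation the adjusted p was 0.699. Adjusted over the list alone 1 gene, Inppl1, passed. Without knockout libraries 1 and 2, which had the lowest ectoderm scores, neither list kept its call, at adjusted p of 0.439 for targets and 0.291 for regulators. Each also lost it without wild type replicate 2 (0.443 and 0.174) and without knockout replicate 1 (0.281 and 0.115), 2 (0.110 and 0.162) or 4 (0.104 and 0.101).

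Epithelial genes were lower in some knockout libraries. Of 33 surface ectoderm and basal epithelium genes, 29 had lower mean values (median log2 difference -0.29, camera adjusted p 3.26e-06), and the adjusted p was 0.746 with an estimated correlation. Their score was 10.01, 10.06 and 10.18 in wild type and 9.43, 9.65, 10.22 and 10.02 in knockout replicates 1 to 4. The lower values came from knockout replicates 1 and 2, and without both the direction turned (adjusted p 0.768). Perp, a desmosomal gene, had 3074 ± 305 against 2359 ± 417 normalized counts, and Trp63, the master regulator of stratified epithelia, had 1914 ± 113 against 1603 ± 276. Pax6 had 1934 ± 248 against 1295 ± 425 and Krt5 7221 ± 994 against 5801 ± 1336; both were used by the submitters to judge libraries and are no independent finding. Of 9 periderm genes 7 had lower values (camera adjusted p 0.340), with Sfn at 3334 ± 229 against 2654 ± 669 and Krt6a at 73.2 ± 38.2 against 92.8 ± 9.25. Among 29 transcription factors of the ocular ectoderm and its glands, 13 had higher and 16 lower values (camera adjusted p 0.489). Adjusted over the list alone 2 of them passed: Barx2, a homeobox gene of glandular epithelia, with 414 ± 46.7 against 240 ± 72.5 (log2 difference -0.83, SE 0.23), and Eya2 with 939 ± 63.1 against 1201 ± 127 (0.35, SE 0.10). Without knockout libraries 1 and 2 the log2 difference was -0.45 for Barx2 and 0.22 for Eya2.

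Among genes of Wnt, FGF and ERK, BMP and TGF-beta, Notch and epithelial-mesenchymal transition lists, 0 passed an adjusted p of 0.1 by limma-trend, over all genes tested or adjusted over the list alone. Of 22 Wnt pathway response genes 15 had lower values (camera adjusted p 0.0507; 0.746 with an estimated correlation), among them Znrf3 at 615 ± 82.4 against 450 ± 74.6 and Wnt4 at 2184 ± 340 against 1625 ± 476 normalized counts. Without knockout libraries 1 and 2 the adjusted p was 0.904. The call was also lost without wild type replicate 4 (0.271) and without knockout replicates 1 (0.128) or 2 (0.268). Of 27 FGF and ERK pathway genes 17 had higher values (camera adjusted p 0.227), with Il17rd at 157 ± 21.7 against 232 ± 55.2 and Dusp4 at 79.6 ± 49.4 against 198 ± 99.5. BMP and TGF-beta response genes (10 of 18 higher, camera adjusted p 0.489) and Notch pathway genes (7 of 14 higher, camera adjusted p 0.922) did not pass. Tgfbi had 230 ± 81.9 against 678 ± 453, and Bmper 40.0 ± 14.7 against 103 ± 60.3. Hes1 had 1122 ± 59.8 against 944 ± 72.2, and Hey1 204 ± 0.711 against 338 ± 139. Regulators of epithelial-mesenchymal transition and mesenchymal readouts had 12 of 16 genes higher (camera adjusted p 0.0746; 0.746 with an estimated correlation), with Itga5 at 327 ± 61.0 against 477 ± 122 and Mmp2 at 727 ± 152 against 1174 ± 381. Without knockout libraries 1 and 2 their direction turned (adjusted p 0.405). The call was also lost without wild type replicate 2 (0.290) and without knockout replicates 1 (0.534) or 2 (0.301).

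Markers of several other cell types had mostly higher mean values in knockout. All 20 tested genes of neurons and neural progenitors had higher mean values (median log2 difference 1.33, camera adjusted p 3.17e-07), as had all 13 endothelial genes (0.80, 1.7e-06) and all 13 macrophage genes (0.92, 7.46e-05); with an estimated correlation the adjusted p of each was 0.699. Nes had 762 ± 171 against 1140 ± 141 normalized counts, and Neurod1 52.97 ± 28.1 against 144 ± 80.4. Pecam1 had 69.2 ± 15.5 against 198 ± 97.4, and Eng 71.5 ± 11.6 against 169 ± 61.3. C1qb had 140 ± 61.2 against 270 ± 79.9, and Aif1 19.7 ± 9.45 against 43.0 ± 7.65. Adjusted over the list alone, 6 endothelial genes and 1 neuronal gene passed, and over all genes tested 0 did. The log2 difference of Pecam1 went from 1.39 to 0.80 and that of Eng from 1.16 to 0.72 without knockout libraries 1 and 2, and that of Nes from 0.60 to 0.40 without wild type replicate 3. Without knockout libraries 1 and 2 the difference of list scores went from 1.35 to 0.97 for neurons, from 0.94 to 0.37 for endothelium and from 0.88 to 0.49 for macrophages, with overlapping libraries. Without wild type replicate 3 it was 0.51 for neurons, 0.80 for endothelium and 0.49 for macrophages. Without both knockout libraries camera gave an adjusted p of 0.00251 for neurons and 0.0485 for both endothelium and macrophages; with an estimated correlation in that setting the adjusted p of each was 0.934. Schwann and melanocyte precursor genes (9 of 11 higher, camera adjusted p 0.0221) and mesenchymal genes (16 of 24 higher, 0.0746) passed, with 0.699 and 0.746 for an estimated correlation, and lost the call without knockout libraries 1 and 2 (0.210 and 0.405, the latter with its direction turned). Kit had 241 ± 19.96 against 375 ± 70.1 and was the single gene of the Schwann and melanocyte list past 0.1 adjusted over the list alone (limma-trend, adjusted p 0.0636). Sox10 had 107 ± 41.6 against 219 ± 98.7. Col1a1 had 1905 ± 234 against 2470 ± 372, and Pdgfrb 280 ± 85.8 against 522 ± 185. Schwann and melanocyte precursors also lost it without wild type replicate 3 (0.169), and mesenchymal genes without wild type replicates 2 (0.708) or 3 (0.122) and knockout replicates 1 (0.436) or 2 (0.466). With depth as a covariate the mesenchymal list also lost it (0.117).

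Erythroid genes went the other way, with 11 of 11 lower (median log2 difference -0.68, camera adjusted p 0.00349, and 0.746 with an estimated correlation). They lost the call without wild type replicate 2 (0.424). The difference of their list scores went from -0.65 to -0.13 without wild type replicate 2 and to -1.19 without wild type replicate 4. Hbb-bt had 14878 ± 9407 against 7409 ± 3389 and Klf1 86.1 ± 55.4 against 47.0 ± 11.8. Haemoglobin genes took 7.01%, 3.97% and 1.84% of wild type reads and 1.61%, 3.88%, 3.34% and 1.83% of knockout reads. Skeletal muscle genes (camera adjusted p 0.161), lens genes (0.426) and retinal genes (0.861) did not pass. Myh3 had 2.44, 0 and 118 normalized counts in wild type and 227, 771, 34.5 and 0.875 in knockout, and Pax7 18.6 ± 8.25 against 12.3 ± 8.64. Prox1 had 45.9 ± 22.1 against 76.2 ± 16.9, and Maf 352 ± 30.5 against 310 ± 36.1. Rlbp1 had 37.1 ± 23.0 against 75.7 ± 41.4, and Atoh7 28.4 ± 30.6 against 8.65 ± 5.61. As scores per library, 0 of the 9 lists of other cell types separated the groups (smallest two-sided exact permutation p = 0.171; smallest adjusted p over all 26 lists 0.557).

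**Figure D3:**
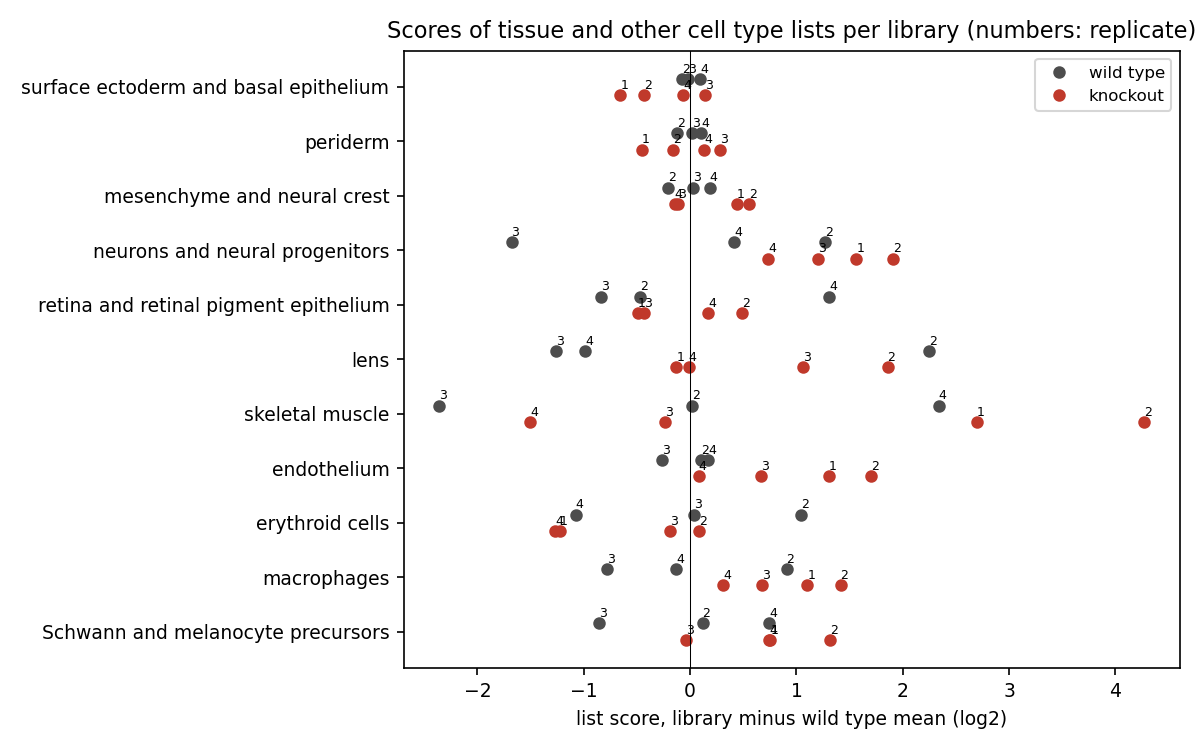
Scores of the 2 lists of ectodermal tissue and the 9 lists of other cell types in each library, as the log2 difference from the wild type mean, with replicate numbers above the points. Knockout replicates 1 and 2 have the lowest ectoderm scores (9.43 and 9.65) and wild type replicate 3 the lowest neuronal score (5.58).

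Genes of DNA replication (19 of 22 lower, camera adjusted p 0.00828) and of mitosis (19 of 20 lower, 0.0174) passed with median log2 differences of -0.10 and -0.06; with an estimated correlation the adjusted p of each was 0.746. Tyms had 2341 ± 230 against 1967 ± 201, and E2f1 566 ± 68.4 against 741 ± 111. Ube2c had 3189 ± 242 against 2756 ± 257, and Cenpf 1334 ± 138 against 1111 ± 162. Both lists lost the call without wild type replicate 3 (0.189 and 0.432), without knockout replicate 2 (0.301 and 0.424) and without knockout libraries 1 and 2 (0.913 and 0.239). Mitochondrially encoded mRNAs had lower mean values for 10 of 12 (median -0.21, camera adjusted p 0.00828, and 0.746 with an estimated correlation). Among them, mt-Nd2 had 8924 ± 642 against 7703 ± 591 and mt-Nd6 3156 ± 617 against 2619 ± 197. The call was lost without knockout replicate 4 (0.281). The share of reads on such mRNAs was 1.265%, 1.21% and 1.34% in wild type. It was 1.44%, 1.37%, 1.28% and 1.03% in knockout replicates 1 to 4, below all wild type libraries only in replicate 4. The p53 response list did not pass (12 of 18 lower, 0.219), and Ccng1, at 1078 ± 70.8 against 862 ± 33.4, was its single gene past 0.1 adjusted over the list alone. Perp is on that list as well. The immediate early and heat shock list (8 of 14 lower, 0.758) and the hypoxia and glycolysis list (10 of 16 lower, 0.560) did not pass either. Dusp1 had 180 ± 16.0 against 279 ± 76.1, and Hspa1b 190 ± 18.4 against 146 ± 35.4. Ndrg1 had 77.4 ± 26.2 against 150 ± 32.7, and Pfkfb3 145 ± 11.3 against 200 ± 30.5. The sex-linked list did not pass (camera adjusted p 0.505), with Xist at 811 ± 610 against 594 ± 385 and Eif2s3y at 150 ± 54.7 against 122 ± 76.1. It joins Xist, a female marker, with the Y-linked Eif2s3y, which can cancel in a directional test, so it does not compare embryo sex. Embryos were not separated by sex in the pools.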

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

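Of 100 measures examined for a library far from the rest of its group, 6 had 1 of the 4 knockout libraries standing apart, and chance alone flags about 1 in 20. Wild type, with 3 libraries, was not examined in this way. Values are log2(normalized count + 1). In knockout replicate 2, Xist was 5.53 where the other knockout libraries were between 9.30 and 9.85, Kit was 8.08 (others 8.64 to 8.71), Pfkfb3 was 7.29 (others 7.72 to 7.79) and Cadm1 was 10.64 (others 10.96 to 10.97). In knockout replicate 4, Lars2 was 15.93 (others 16.16 to 16.19) and the score of mitochondrially encoded mRNAs was 10.83 (others 11.15 to 11.19). No explanation of these 6 values was tested.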

How the results depend on the processing

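The settings without knockout libraries 1 and 2, the depth covariate, the shrunken DESeq2 fit, and the estimated correlation combined with another setting were chosen after seeing the data. The count of called genes was 0 by limma-trend (unadjusted p under 0.05 for 1469). It stayed 0 with pseudocounts of 0.5 and 5, without a filter, with TMM or upper-quartile scaling, at a threshold of 0.05, and by edgeR with a filter and by limma-voom. It was 227 by DESeq2 (199 shared with the authors' calls), 206 with shrunken coefficients, 11 by edgeR without a filter, 2 with the submitters' filter, 11 with the depth covariate, and 3 without knockout libraries 1 and 2. Leaving out 1 library gave between 0 and 84. The cause was not tested, but simulated counts gave DESeq2 34.4% false calls and limma-trend 14.4%. With a replicate block it was 3 and 11 gene lists passed (10 shared). The numbers are not said to pair the libraries; correlations of same-numbered deviations were 0.097, 0.111 and -0.011, and only wild type replicate 2 correlated best with its own number. The seed-site difference moved from 0.065 to between 0.053 and 0.076 when 1 library was left out, 0.054 without knockout libraries 1 and 2, and within the libraries over 10000000 reads it was 0.065; all alternatives kept its direction. The number of lists past camera was 14. It was 0 with an estimated correlation, 0 by fry's directional test (3 by its mixed test: literature targets and PI3K regulators, each 0.0685, and p53 response, 0.0718), 0 with an estimated correlation and replicate block or without knockout libraries 1 and 2, 8 without those libraries at the preset correlation (5 shared), 13 with the depth covariate (all shared), and between 7 and 18 with 1 library left out. The number of separated other-cell lists was between 0 and 3 with 1 library left out. For named genes, 1482 of 1558 comparisons over 68 genes kept direction and side, 58 gained a call and 18 turned direction. For lists, 274 of 415 comparisons stayed, 89 lost and 12 gained a call, and 40 turned direction.

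None of the genes that turned direction was called. The log2 fold change of Zeb2 turned to -0.046 (voom), -0.22 (replicate block), -0.064 (depth covariate) and -0.65 (without knockout libraries 1 and 2), and the log2 fold change of Inpp4b, to -0.083, -0.035, -0.10 and -0.56 in the same order; Xist turned to 0.35 without knockout libraries 1 and 2. With 1 library left out, Zeb2 was between -0.22 and 0.39, Inpp4b between -0.27 and 0.53, Krt6a between -0.025 and 0.84 and Xist between -1.35 and 0.21. Adjusted p of lists that turned without knockout libraries 1 and 2, with the estimated correlation second, was 0.768 and 0.978 for ectoderm, 0.158 and 0.934 for periderm, 0.405 and 0.934 for epithelial-mesenchymal transition, 0.405 and 0.942 for mesenchyme, 0.0485 and 0.934 for skeletal muscle, 0.474 and 0.942 for immediate early genes, 0.0987 and 0.934 for hypoxia, and 0.960 and 0.978 for Notch. With a replicate block, preset then estimated, it was 0.932 and 0.964 for retina, 0.820 and 0.964 for hypoxia, and 0.932 and 0.964 for Notch; Notch also turned by fry (0.968) and retina with the submitters' filter (0.648). With 1 library left out, the adjusted p of lists that turned in any such fit was between 0.0623 and 0.993 (ocular ectoderm factors), 0.0266 and 0.929 (periderm), 0.0491 and 0.985 (retina), 0.00527 and 0.957 (lens), 0.00342 and 0.985 (skeletal muscle), 0.411 and 0.985 (immediate early genes), 0.186 and 0.957 (hypoxia), 0.290 and 0.957 (BMP and TGF-beta), 0.189 and 0.929 (Notch), and 0.0859 and 0.993 (sex-linked). The cause of these turns was not tested. Depth limits genes with few reads, and 7 libraries limit every test here.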

Other observations

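Messages of the translation and respiration machinery had lower mean values in knockout. The lists in this paragraph, and the tests of ribosomal protein genes, of other cell types, of base composition, of site classes and of other splits, and the matching of respiratory chain, Sm and LSm and histone genes, were chosen after the results were seen; the matched tests of ribosomal protein and seed-site genes were fixed before their results were seen. All 81 ribosomal protein genes tested had lower mean values (median log2 difference -0.24), with list scores of 12.28, 12.40 and 12.41 in wild type and 12.11, 12.18, 12.12 and 12.07 in knockout (two-sided exact permutation p = 0.0571, the smallest possible). Nuclear-encoded respiratory chain genes were lower for 69 of 73 (-0.16), Sm and LSm proteins of the splicing machinery for 18 of 20 (-0.17) and replication-dependent histones for 28 of 37 (-0.32), each with all knockout libraries below all wild type libraries. These messages are short, with median transcript lengths of 861, 1092 and 630 nt against 3094 nt for tested genes. Relative to other genes of matched length and expression, the score difference of respiratory chain genes went from -0.12 to 0.01 and that of histones from -0.28 to -0.38, both with overlapping libraries. The genes matched to histones (median 681 nt) had mean values higher by 0.094 in knockout, with overlapping libraries (two-sided exact permutation p = 0.686). That of Sm and LSm proteins went from -0.16 to -0.08 with no overlap (two-sided exact permutation p = 0.0571, the smallest possible). The share of reads on Rn18s-rs5, Lars2, Gm26917, Gm42418, mt-Rnr1 and mt-Rnr2, ribosomal RNA genes or genes that can collect such reads, was also lower in knockout, at 2.10%, 2.25%, 2.05% and 1.88% against 2.47%, 2.62% and 3.29%. In the authors' deposited table, ribosomal proteins are encoded by 46 of the 167 genes called lower, and by 0 of the genes called higher. Sterol synthesis genes were higher for 18 of 21 (median 0.12), with overlapping libraries (two-sided exact permutation p = 0.114). Other scalings moved group differences by at most -0.031 and changed the direction of none of these lists.

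Pattern and tests for ribosomal protein genes: the score was lower by -0.24 in knockout. Their messages are short (median 906 nt), the authors' lower calls have a median transcript length of 1163 nt against 4139 nt for higher calls. Other genes of matched length and expression were lower too, by -0.15, which leaves -0.094 with overlapping libraries, so a loss of short transcripts in knockout libraries may account for part of it. Less ectoderm in knockout libraries 1 and 2 as the whole cause is argued against, since the unmatched difference was -0.27 without those libraries. It was -0.31 within the libraries over 10000000 reads and -0.13 within the others, classes too small for a test. The part left after matching turned direction with depth. Over 10000000 reads its values were 0.181 and 0.253 in wild type and 0.021 and 0.029 in knockout. In the others they were 0.037 in wild type replicate 2 and 0.098 and 0.1045 in knockout replicates 1 and 2. Depth as a cause of that part stays open. An effect of the knockout itself on translation genes stays open.

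Markers of neurons, endothelium and macrophages were higher in knockout by a mean score of 1.06, with overlapping libraries. If a smaller share of ectoderm alone raised them, erythroid markers would follow; the endothelial minus erythroid score was higher in knockout by 1.59, but its libraries overlapped and the test does not decide. Without knockout libraries 1 and 2 the mean score was higher by 0.61, with overlap, and the endothelial score went from 0.94 to 0.37, so neighbouring tissue in those libraries alone cannot be told apart from a wider difference because 2 and 3 libraries are left. Without wild type replicate 3 alone the mean score was higher by 0.60, a fall as large. The muscle gene Actc1 had 5696 normalized counts in knockout replicate 2 and 43.8 in knockout replicate 4. In wild type it had 896 in replicate 4 and 11.2 in replicate 3. The lens gene Cryaa had 2342 in wild type replicate 2 and 12.2 in wild type replicate 4. The neuronal gene Tubb3 was between 228 and 5513 over all libraries. Markers of other tissues thus varied within both groups. A change of neurons, endothelium or macrophages in the knockout stays open.

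Higher values of seed-site messages in knockout kept their direction in each test. Against genes matched on 3′ UTR length and expression the difference fell from 0.065 to 0.035, so these properties account for part of it, and random gene sets gave an SD of 0.012 around 0. Base composition as the cause is argued against by the control 7-mers, of which a share of 0.00719 (1 of 139) reached the matched difference. Other cells in knockout libraries 1 and 2 alone are argued against by an unmatched difference of 0.054 without them. Scores of neurons, endothelium and macrophages stayed higher by 0.97, 0.37 and 0.49 without those libraries. The test therefore cannot decide whether other cells captured across the knockout libraries contribute. Sites with an 8mer exceeded those with a 7mer-m8 by 0.036 more in knockout than in wild type, in the order of strength that loss of the microRNA predicts. The groups did not overlap in this excess but nearly met. Knockout replicate 4 had 0.0296 for 8mers and 0.0206 for a 7mer-m8 alone, and wild type replicate 3 had -0.0193 and -0.0271. As a hypothesis, these values are consistent with loss of miR-205 activity in the knockout libraries, found and tested on the same 7 libraries.

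The count of limma-trend calls was 0 (highest other 4), which all 35 splits of the 7 libraries reach, so it decides nothing. Over all 35 splits, chance could not be excluded for the other counts. Of the 35 splits, 3 gave as many genes with an unadjusted limma-trend p under 0.05 (1469; highest other 1939), 13 gave as many gene lists (14; highest other 19), and 3 gave as many DESeq2 calls over genes with at least 70 reads (228; highest other 534). The split with 534 and 1939 sets wild type replicate 2 and knockout replicates 1 and 2 apart, the 3 libraries under 10000000 reads. In that order, they also had the highest neuronal scores (8.52, 8.82 and 9.17, others at most 8.455). The same held for macrophage scores (6.71, 6.90 and 7.215, others at most 6.475). Their ectoderm scores were the lowest (10.01, 9.43 and 9.65, others at least 10.02). Depth and captured tissue therefore cannot be told apart in this split, the 18 splits below or the depth covariate. Among the 18 splits that, like the real one, put 1 of those 3 libraries in the group of 3, the real split had the most DESeq2 calls (228; highest other 64) and the most genes with an unadjusted limma-trend p under 0.05 (1469; highest other 824), while 6 had as many gene lists (14; highest other 16). These 18 splits were picked out after the counts were seen and are too few for a share under 0.05. With depth as a covariate limma-trend called 11 genes, 8 higher and 3 lower, 9 of them among the authors' calls.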
